A study of Danio rerio with 6 samples.

How the data were processed

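Gene expression was measured by poly(A)-selected, non-stranded, paired-end RNA sequencing (read length 100 bases, DNBSEQ platform) of zebrafish larvae at 5 dpf. Per the labels, larvae came from in-crosses of heterozygous hspd1 carriers, were genotyped, and were pooled by 5, and the pooling was repeated for 3 mating sets. The groups, control (hspd1+/+) and hspd1 knockout (hspd1−/−), were taken from the labels, with 3 pools each. The replicate numbers were used as names of the pools.

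The deposited values are estimated counts per gene, stored as whole numbers, for 25859 Ensembl genes in each of 6 files. Per the submitters' processing notes, FastQC, Trim Galore, Salmon and DESeq2 were used with the genome build GRCz11, and neither versions nor the role of each tool are given in the sources used here. Because the values were whole already, rounding before the count tests changed nothing. Total counts ran from 18517874 to 20331675 per pool, with 23801 to 23946 genes above 0 and 9.07% to 10.3% of counts in the top 10 genes. Replicate pools differed by more than counting noise (chi-square over its degrees of freedom 7.41 to 21.4 within groups), so each was counted as 1 sample, and their Pearson correlation on log CPM across genes was 0.983 to 0.989.

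Gene symbols came from a table of gene IDs and symbols, which gave a symbol for 23598 of the 25859 genes. Symbols are printed as that table gives them, and 11854 are in the capitals of human symbols. A symbol is carried by more than 1 gene for 3608 genes, and an ID is printed where a named symbol could be mistaken. Genome positions are not given, because the positions at hand belong to another build. Without strand information, reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads of similar paralogs may be split between them.

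Genes were kept by edgeR's filterByExpr (21602 genes, with 0.0516% of counts removed), and libraries were scaled by the trimmed mean of M-values (TMM, factors 0.970 to 1.03). Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 12.7%. Standard errors (SE) of log2 fold changes were derived from the test, as the absolute log2 fold change over the square root of its F statistic. CPM are TMM-scaled, and log CPM used a prior count of 2. The same test was tested on simulated data made from the means and library sizes of this comparison, over 21469 genes. It recovered 83 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2, with 14 false calls among 195.

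Before the data were examined, 55 gene lists of pathways, protein complexes and cell type markers were fixed, with 1552 written members, of which 95 matched no gene. Each list with at least 5 tested genes was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 55 lists, and beside it with an estimated correlation and with fry. Counts of members are given over all genes tested and adjusted over the list alone. Single quantities per pool were compared by exact two-sided permutation tests, which with 3 against 3 pools cannot go below 0.1.

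The genes named were also set by a rule fixed before the data were examined. They are hspd1, then the 8 higher and 8 lower genes with the largest fold change among those past the threshold with a symbol, a mean of at least 1 CPM and no overlap between groups, up to 4 genes per list by smallest p, and 12 preset genes of the mitochondrial stress response. The rule took 239 genes, not all of which are printed, and some results are not reported here. A further 26 genes were chosen after their values were seen, among them fabp10a, hpxa, hamp, apobb.1, BHMT, RBP4, PTF1A, DDIT4, pck2, HTRA2 and c3a.2, as were c3a.3, c3b.1, SLC25A38 and mt-nd4l. A gene with 0 reads in a group was compared with a floor of 3 counts over the group, and a gene with 1 to 3 reads is given as a ratio with a 95% exact binomial interval. Floors and intervals cover counting error only.

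Alternatives were other scalings (RLE and upper quartile), no filter, a filter of 1 CPM in 3 pools, an adjusted p of 0.01, a minimum fold change of 2, the replicate number as a block, each pool left out in turn, DESeq2 1.42.0 and limma-voom.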

Results

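Transcript levels were measured in zebrafish (Danio rerio) larvae at 5 days post fertilization (dpf) that carried either 2 functional copies of hspd1 or a homozygous knockout of it. The gene hspd1 codes for HSP60, the chaperonin that folds imported proteins in the mitochondrial matrix together with its co-chaperonin HSPE1 (HSP10). The series holds 6 poly(A)-selected libraries, 3 per genotype, each made from a pool of 5 genotyped larvae from in-crosses of heterozygous carriers. The libraries held 18517874 to 20331675 counts over 25859 genes, with 20331675, 18873172 and 18853982 counts in control pools 1, 2 and 3 and 19131375, 18745969 and 18517874 counts in the knockout pools 1, 2 and 3. The comparison of genotypes asks which transcripts differ in larvae with the homozygous knockout. All fold changes below are knockout over control, with n = 3 pools per group.

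The targeted gene was lower in every knockout pool. Normalised levels of hspd1 (ENSDARG00000056160) were 124, 133 and 132 CPM (counts scaled to library size) in control pools 1, 2 and 3 and 73.4, 67.9 and 82.3 CPM in knockout pools 1, 2 and 3, or 129 ± 5.02 CPM against 74.5 ± 7.29 CPM (mean ± SD, n = 3). The log2 fold change was −0.79 (SE 0.11, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00162). Transcript of the gene thus remained in every knockout pool, and HSP60 protein was not measured. Its partner HSPE1 stood at 72.5 ± 2.76 CPM in the controls and 80.8 ± 0.321 CPM in the knockouts, a log2 difference of 0.15 that did not pass the test (edgeR adjusted p = 0.478). HSPA9, the mitochondrial HSP70, rose from 186 ± 8.65 CPM to 349 ± 23.9 CPM, and LONP1, the matrix protease that degrades misfolded proteins, rose from 24.1 ± 2.21 CPM to 39.1 ± 2.00 CPM.

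**Figure D1:**
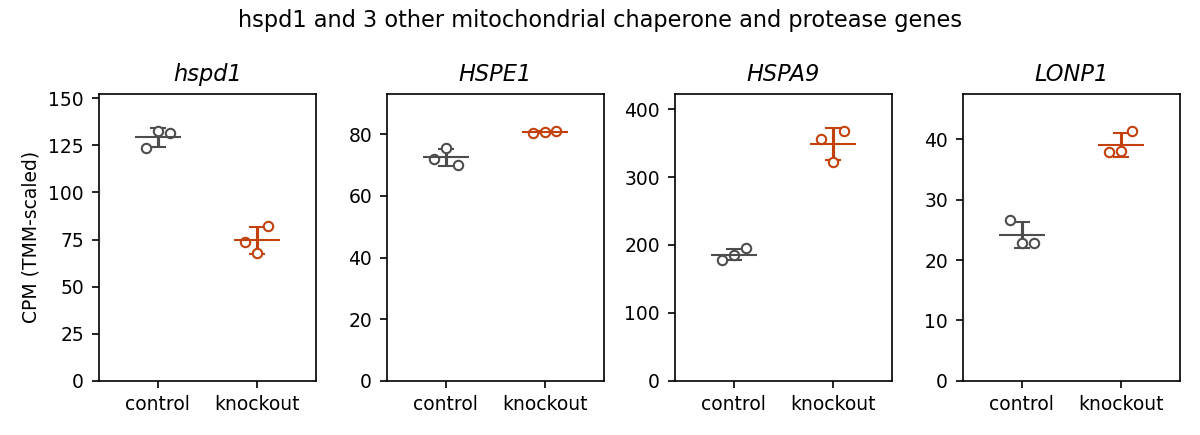
TMM-scaled CPM (vertical axes, each from 0) of hspd1 and of HSPE1, HSPA9 and LONP1 in the 3 control and 3 knockout pools; open circles are pools, and bars are the mean and SD. The 3 knockout pools sit at 67.9 to 82.3 CPM for hspd1, below the controls at 124 to 133 CPM, while HSPA9 and LONP1 sit higher in every knockout pool.

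Large decreases were measured for single genes. ahsg2, a fetuin of the blood plasma, had 351 reads over the control pools and 0 over the knockout pools, so it was at least 118-fold lower (against a floor of 3 counts over the group). The other large decreases were itln3 (an intelectin, a lectin of innate defence), with a log2 fold change of −6.99, si:ch211-288g17.4 (−6.92), and the pentraxin genes apcs (−6.75) and crp5 (−5.97). ebi3, a subunit of cytokines of the interleukin-12 family, had a log2 fold change of −5.84. serpina7, named for the human thyroxine-binding globulin, had 318 reads in the controls and 3 in the knockouts, a ratio of 107 (95% exact counting interval 36.3 to 522), and si:ch73-15n24.1 had 282 and 3 reads, a ratio of 94.9 (interval 32.1 to 463).

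On the higher side, isg15, an interferon-induced ubiquitin-like modifier, rose from 0.405 ± 0.114 CPM to 27.9 ± 13.1 CPM, and RSAD2, the antiviral enzyme viperin, rose from 0.543 ± 0.235 CPM to 19.1 ± 14.0 CPM. The interferon-induced genes ifit14 and mxe rose by 6.50 (SE 0.99) and 4.58 (SE 0.71) on the log2 scale, and ifit8 had 3 reads in the controls against 125 in the knockouts, a ratio of 41.3 (95% exact counting interval 13.8 to 203). igldcp and si:ch211-76m11.7 rose by 6.14 and 6.25 on the log2 scale, and si:ch211-127n13.2 had 2 reads in the controls against 403 in the knockouts, a ratio of 199.6 (interval 54.9 to 1654).

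Of 21602 genes tested, 866 (4.01%) passed an adjusted p of 0.05, of which 317 were higher and 549 lower in the knockout pools. At least 2-fold changes were seen for 389 of them, 121 higher and 268 lower. All 866 had no overlap between the 3 knockout and 3 control values, which passing this threshold with 3 pools per group largely requires. Of all tested genes 4622 (21.4%) had no overlap, against 10% by chance. The first principal component held 50.1% of the variance and separated the genotypes. The number of calls was 566 without control pool 2 and 549 without control pool 3, the number higher was 203 without knockout pool 2, and upper-quartile scaling gave 415 higher and 476 lower genes.

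Of 34 tested genes of the exocrine pancreas, which makes the digestive enzymes, 28 fell and none rose (31 fell when p-values were adjusted over the list alone), with a median log2 fold change of −2.46. Their summed level was 10036 ± 2509 CPM in the controls and 2327 ± 265 CPM in the knockouts. The trypsin gene prss59.1 fell from 517 ± 152 CPM to 61.6 ± 0.281 CPM, the astacin-type protease gene c6ast4 fell from 214 ± 78.6 CPM to 9.62 ± 2.56 CPM, and the elastase gene ela3l fell from 345 ± 96.4 CPM to 47.4 ± 6.80 CPM. PTF1A, the acinar transcription factor, stood at a log2 difference of −0.81 that did not pass the test (edgeR adjusted p = 0.109). The list passed camera with its preset correlation (adjusted p = 1.73e-45), with an adjusted p = 0.207 with an estimated correlation. Several of these enzymes belong to families of similar genes (elastases, chymotrypsins, carboxypeptidases and amylases), so the split of reads within such families is uncertain.

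Of 37 tested hepatocyte genes, 26 fell and 1 rose (29 and 1 adjusted over the list alone), with a median log2 fold change of −1.03, which was also −1.03 with ahsg2 at its bound. TTR, a carrier of thyroid hormone, fell from 31.5 ± 0.121 CPM to 1.55 ± 0.348 CPM, shbg, the sex hormone-binding globulin, from 45.9 ± 7.15 CPM to 1.43 ± 0.434 CPM, uox, the urate oxidase, by a log2 fold change of −4.13 (SE 0.18), and GC, the vitamin D-binding protein, from 54.7 ± 6.56 CPM to 2.64 ± 0.963 CPM. fabp10a, the liver fatty acid-binding protein, fell by 2.41 on the log2 scale. At the other end apobb.1, BHMT and RBP4 stood at log2 differences of 0.02, 0.05 and 0.02, which did not pass the test (edgeR adjusted p = 0.973, 0.902 and 0.966). The gene that rose was hamp, the iron hormone hepcidin, at a log2 fold change of 3.98. The list's camera adjusted p was 1.58e-33 with the preset correlation, and its adjusted p = 0.188 with an estimated correlation.

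Of 38 genes of absorptive intestinal cells, 15 fell and none rose (20 fell and 1 rose adjusted over the list alone), with a median log2 fold change of −0.52. They included the peptide transporter gene SLC15A1 (ENSDARG00000044528), which fell from 152 ± 7.52 CPM to 65.1 ± 15.5 CPM, the brush border gene VIL1, from 413 ± 55.6 CPM to 206 ± 33.9 CPM, and the chitinase gene chia.2, which fell by 1.64 on the log2 scale. The camera adjusted p was 7.92e-09, and the adjusted p = 0.568 with an estimated correlation. Without control pool 3, 9 of these genes passed. Among 18 genes of the endocrine pancreas, 2 rose and none fell, both of them glucagon genes: gcga from 16.9 ± 1.61 CPM to 40.8 ± 2.67 CPM, and GCG with a log2 fold change of 0.69. The endocrine list did not pass camera (adjusted p = 0.376).

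**Figure D2:**
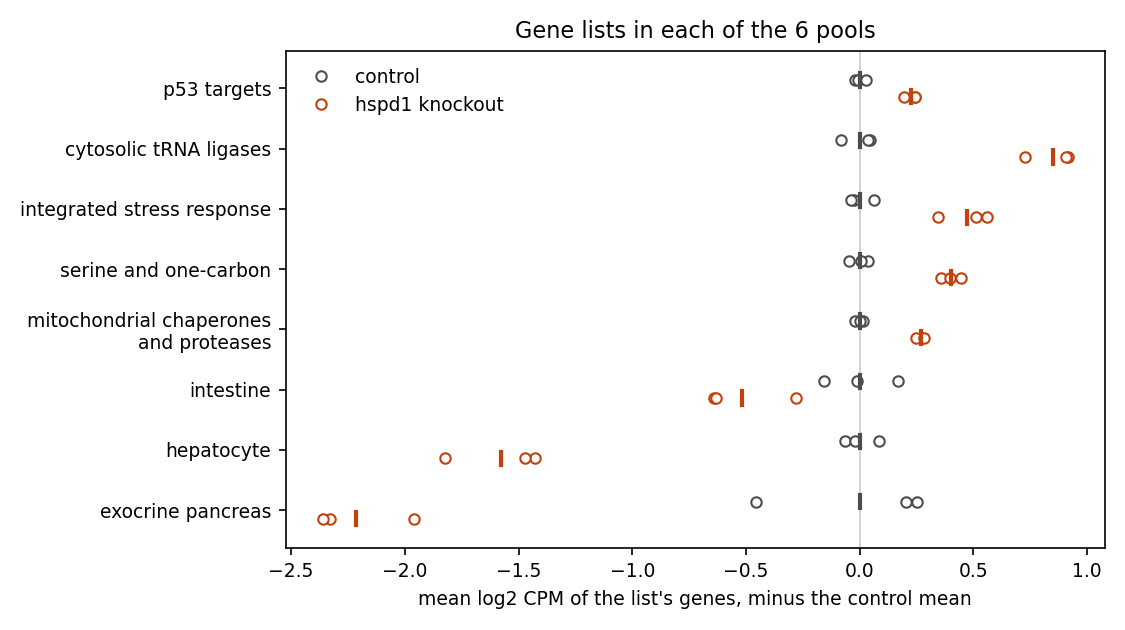
Mean log2 CPM of the genes of 8 lists in each pool, minus the control mean (horizontal axis); open circles are pools and vertical ticks are group means. The hepatocyte list sits at −1.83 to −1.43 in the 3 knockout pools and the exocrine pancreas list at −2.36 to −1.96, while the cytosolic tRNA ligases sit at 0.73 to 0.91.

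Cytosolic tRNA ligases, which load amino acids onto tRNAs, rose in 16 of 19 genes with none falling (18 adjusted over the list alone), with a median log2 fold change of 0.82. KARS1 rose from 225 ± 18.4 CPM to 766 ± 56.8 CPM, a 3.41-fold increase, and YARS1, TARS1 and AARS1 rose by log2 values of 1.36, 1.26 and 0.98. The camera adjusted p was 2.06e-27, and the adjusted p = 0.188 with an estimated correlation. Among 16 mitochondrial tRNA ligases 1 rose, HARS2 with a log2 fold change of 0.87, and that list did not pass (camera adjusted p = 0.225). The cytosolic and mitochondrial lists shared 0 genes, so a ligase gene that serves both compartments would count in 1 of them only.

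The list of the integrated stress response and its transcription factor ATF4 had 38 tested genes, of which 14 rose and 2 fell (21 and 4 adjusted over the list alone), with a median log2 fold change of 0.40. ppp1r15b, a subunit of the phosphatase that acts on the initiation factor eIF2 alpha, rose from 4.81 ± 0.754 CPM to 22.2 ± 1.86 CPM, and the neutral amino acid transporter gene SLC1A4 rose from 23.5 ± 1.57 CPM to 102 ± 14.3 CPM. atf5b, sesn2, atf5a and DDIT3 rose by log2 values of 1.64, 1.90, 0.68 and 0.72. The ATF4 genes themselves did not pass the test, at a log2 difference of 0.43 for atf4a (edgeR adjusted p = 0.0825) and 0.32 for atf4b (adjusted p = 0.213), but atf4a passed with DESeq2 (0.0188) and with upper-quartile scaling (0.0437). The genes that fell were DDIT4, an inhibitor of mTORC1, and pck2, the mitochondrial PEP carboxykinase, with log2 fold changes of −0.77 and −0.49, and neither passed without control pool 3, knockout pool 1 or knockout pool 2. Without control pool 2 or knockout pool 3, 1 of them fell. The list's camera adjusted p was 1.91e-11, and its adjusted p = 0.246 with an estimated correlation.

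Serine and one-carbon genes rose in 7 of 21 cases with none falling (11 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.31. PSAT1 and PHGDH, enzymes of serine synthesis, rose 4.04-fold and 2.47-fold, and ALDH1L2, a mitochondrial folate enzyme, and ASNS, the asparagine synthetase, rose by log2 values of 1.09 and 0.94. The mitochondrial folate enzyme gene mthfd2 stood at 0.60 and did not pass (edgeR adjusted p = 0.0733), but it passed with DESeq2 (0.0144), with upper-quartile scaling (0.0422) and without knockout pool 2 (0.0166). The list's camera adjusted p was 4.98e-07, and its adjusted p = 0.188 with an estimated correlation. Without control pool 2, and likewise without control pool 3, 4 of these genes rose, and 1 gene fell without control pool 1 and 1 without knockout pool 1.

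Of 28 genes of mitochondrial chaperones and proteases, 6 rose and none fell (7 adjusted over the list alone), with a median log2 fold change of 0.21. This list did not hold hspd1 itself, which fell. Besides HSPA9 and LONP1 these were PMPCB, a subunit of the peptidase that removes import signals, from 22.3 ± 2.34 CPM to 46.0 ± 8.49 CPM, dnaja3b (log2 fold change 0.65) and, of 5 genes with the symbol HTRA2, a protease of the intermembrane space, ENSDARG00000069909 (0.73) and ENSDARG00000111633 (1.08). dnaja3b did not pass without knockout pool 3 (edgeR adjusted p = 0.0517). The HTRA2 gene ENSDARG00000069909 did not pass without control pool 3 or knockout pool 3 (0.0683 and 0.0525). ENSDARG00000111633 did not pass without control pool 1, knockout pool 1, control pool 2, knockout pool 2 or control pool 3 (0.0548 to 0.107), nor with DESeq2 (0.0782). The camera adjusted p was 1.21e-06, and the adjusted p = 0.246 with an estimated correlation. Of 25 p53 target genes 5 rose and none fell (8 adjusted over the list alone), among them CCNG1 and mdm2 with log2 fold changes of 0.78 and 0.67 (camera adjusted p = 1.27e-04, and adjusted p = 0.188 with an estimated correlation). The count of p53 targets was 2 without control pool 3 or knockout pool 2, and 3 without control pool 1, control pool 2 or knockout pool 3. The counts of none given so far are those of edgeR. At an unadjusted p under 0.05, 2 intestinal genes were higher, and 2 endocrine pancreas and 2 serine and one-carbon genes were lower, with 0 in the other lists. DESeq2 and limma-voom gave 0 in these lists as well, except for 1 serine and one-carbon gene lower with DESeq2.

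**Figure D3:**
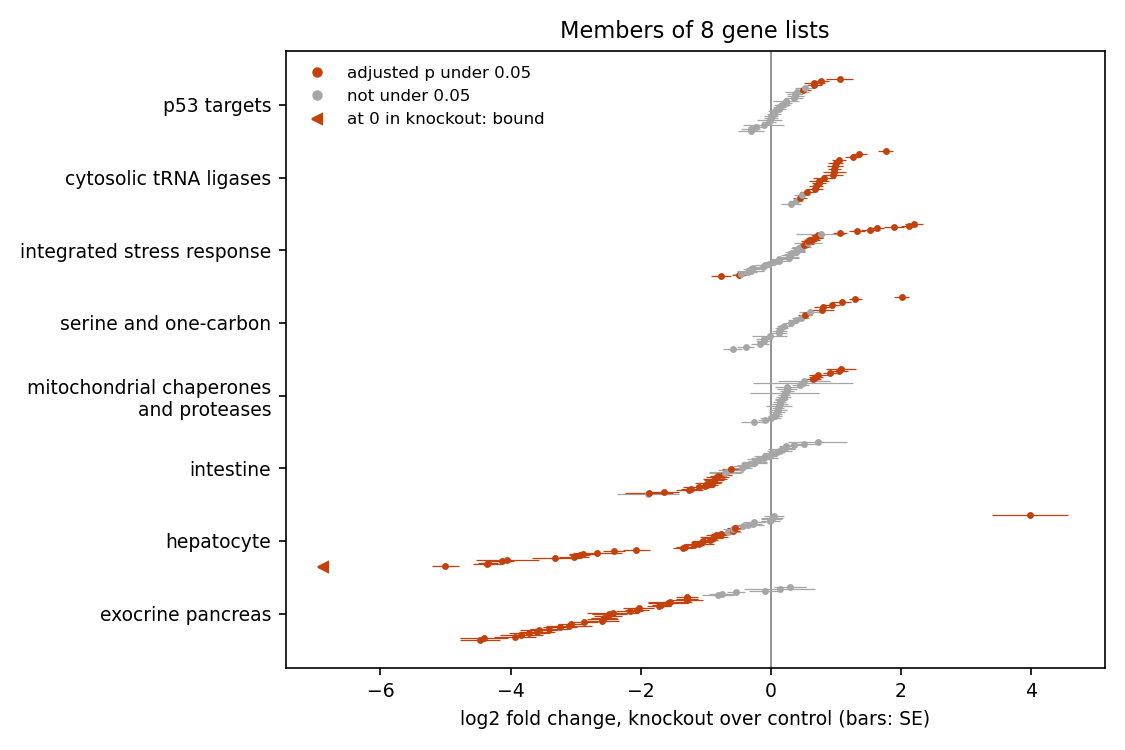
Log2 fold changes, knockout over control (horizontal axis, bars are SE), of each tested member of 8 lists, sorted within a list; coloured points passed an adjusted p of 0.05, and the triangle is the bound for ahsg2, which had 0 reads in the knockout pools. Exocrine pancreas genes reach from −4.47 to 0.30, while 16 of 19 cytosolic tRNA ligases passed, all above 0.

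Of 34 genes of iron-sulfur cluster and heme synthesis, 6 fell and 2 rose (10 and 3 adjusted over the list alone), with a median log2 fold change of −0.09 (−0.17 without knockout pool 1, −0.04 with upper-quartile scaling). ALAS1, the first enzyme of heme synthesis, fell with a log2 fold change of −1.22 (SE 0.15), and the later enzymes CPOX, PPOX and UROD fell with log2 fold changes of −0.96, −0.93 and −0.82. ISCA1, an iron-sulfur assembly factor, rose from 52.9 ± 6.06 CPM to 115 ± 21.4 CPM, and the other gene that rose was SLC25A38, the mitochondrial glycine carrier. The list's camera direction was lower (adjusted p = 0.00874, and adjusted p = 0.568 with an estimated correlation). Without knockout pool 1, 10 genes fell, and the number that rose was 1 without knockout pool 1, knockout pool 2 or control pool 3. Without knockout pool 2 the list did not pass (camera adjusted p = 0.0512).

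Of 17 erythroid genes, of which 3 also stand in the iron-sulfur and heme list, 3 fell (9 adjusted over the list alone): SLC4A1 (ENSDARG00000012881), the band 3 anion exchanger, UROD and klf1, an erythroid transcription factor, with log2 fold changes of −1.75, −0.82 and −1.18 (camera adjusted p = 1.89e-05, and adjusted p = 0.568 with an estimated correlation). That count was 8 without knockout pool 1, 5 without control pool 2 and 6 with DESeq2, and klf1 did not pass without knockout pool 2 (edgeR adjusted p = 0.0521) or control pool 3 (0.061). Of 6 embryonic globin genes 3 fell, hbae1.3, hbae1.2 and hbae1.1, with log2 fold changes of −0.77, −0.91 and −0.70 (camera adjusted p = 0.00598, and adjusted p = 0.568 with an estimated correlation). No globin gene of this list passed without control pool 3, knockout pool 2 or knockout pool 3, and 1 passed without control pool 2. hbae1.1 did not pass with upper-quartile scaling (edgeR adjusted p = 0.0658). The list did not pass without knockout pool 2 (camera adjusted p = 0.0771), and the globins are similar copies, so the split of reads between them is uncertain.

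Of 22 lipid transport genes 6 fell and none rose with edgeR (10 and 2 adjusted over the list alone; 3 were higher at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom), among them apobb.2, a form of apolipoprotein B, and apoa1b, of high-density lipoprotein, with log2 fold changes of −2.66 and −1.03 (camera adjusted p = 0.00899, and adjusted p = 0.568 with an estimated correlation), and 4 of the 22 are also hepatocyte markers. The count was 3 without control pool 2, control pool 3, knockout pool 2 or knockout pool 3, and the list did not pass without control pool 2 (camera adjusted p = 0.108). Of 27 cholesterol synthesis genes 2 fell (17 fell and 1 rose adjusted over the list alone), the sterol reductase gene TM7SF2 and HMGCS1, which makes HMG-CoA, with log2 fold changes of −1.62 and −1.85. HMGCS1 did not pass without knockout pool 1, 2 or 3 (edgeR adjusted p = 0.135, 0.081 and 0.104), nor with DESeq2 (0.0677). That list had a median log2 fold change of −0.69 (−0.42 without control pool 2) and a camera adjusted p of 1.15e-07, and its adjusted p = 0.568 with an estimated correlation. Control pool 2 stood apart in it, with a mean log2 level of 0.73 against −0.44 and −0.28 in control pools 1 and 3 and −0.83, −0.48 and −0.91 in the knockout pools (from the control mean). Its count was 10 without control pool 1, 4 without control pool 3 and 1 without knockout pool 1 or knockout pool 3.

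Cell cycle genes had a median log2 fold change of −0.41 (−0.22 without control pool 2), and 3 of 39 fell (11 adjusted over the list alone): the mitotic genes plk1, espl1 and bub1, with log2 fold changes of −0.83, −0.66 and −0.69. The camera adjusted p was 7.07e-09, and the adjusted p = 0.579 with an estimated correlation. The pools overlapped, at mean log2 levels of −0.33, 0.31 and 0.01 in control pools 1, 2 and 3 and −0.42 to −0.29 in the knockouts. bub1 did not pass with upper-quartile scaling (edgeR adjusted p = 0.0562). Without control pool 1, 12 of them fell, with DESeq2 7, and without control pool 2, control pool 3, knockout pool 1 or knockout pool 3 the count was 1. Among 37 neural progenitor genes 6 fell and 1 rose (7 and 2 adjusted over the list alone). The gene that rose was nes, the intermediate filament nestin, from 29.6 ± 2.55 CPM to 125 ± 12.3 CPM, and those that fell included the neurogenic factor genes INSM1 (ENSDARG00000091756) and HES6. The progenitor list's camera adjusted p was 0.035 and its adjusted p = 0.568 with an estimated correlation. The number that rose was 2 without control pool 1. Only 1 gene of the list fell without control pool 2, control pool 3 or knockout pool 2, and 3 fell without knockout pool 3 or with upper-quartile scaling. The list did not pass without control pool 2 (camera adjusted p = 0.131) or knockout pool 1 (0.0513), nor with the replicate block (0.0507).

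Camera also called 8 further lists. The inflammation list had 30 tested genes, of which 8 rose and 4 fell (12 and 5 adjusted over the list alone). Those that rose included isg15, RSAD2 and IRF7, all of the interferon response, and those that fell were the complement genes c3a.2, c3a.3, c3b.1 and c3b.2. Its camera adjusted p was 8.28e-04 and its adjusted p = 0.568 with an estimated correlation, and 5 genes rose without control pool 2, control pool 3 or knockout pool 2. hamp, also a hepatocyte marker here, is among the genes that rose. In the macrophage list 1 of 23 genes rose, MFAP4 (ENSDARG00000088745), which did not pass without control pool 3 or knockout pool 2 (0 genes), while 2 rose without control pool 1 (camera adjusted p = 0.00461, and adjusted p = 0.246 with an estimated correlation). In the neuronal list 2 of 44 genes fell, tubb5 and map2 (camera adjusted p = 0.0036, and adjusted p = 0.653 with an estimated correlation), and the count was 0 without control pool 2 or control pool 3, 1 without knockout pool 1 or knockout pool 2, and 4 without knockout pool 3. Without knockout pool 1 that list did not pass (camera adjusted p = 0.0719).

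In the lens list 1 of 54 genes fell, the crystallin gene CRYAA, and the count was 0 without control pool 1, control pool 2, knockout pool 1 or knockout pool 3 and 2 without control pool 3 (median log2 fold change −0.23, or −0.15 without control pool 2, camera adjusted p = 1.16e-05, and adjusted p = 0.75 with an estimated correlation). Its mean log2 level in control pool 3 (−0.25) lay within those of the knockouts (−0.34 to −0.11). Among 92 cytosolic ribosome genes, a name match that also took in ribosomal S6 kinases, 1 rose. It was rps27l, known as a p53 target, from 14.1 ± 1.61 CPM to 52.0 ± 3.66 CPM. That list had a median log2 fold change of 0.09 (0.04 without control pool 1, 0.02 without knockout pool 1, 0.16 without control pool 2 or knockout pool 3, 0.14 with upper-quartile scaling; camera adjusted p = 9.76e-04, and adjusted p = 0.841 with an estimated correlation). No single gene passed with edgeR in 3 lists that camera called higher: autophagy (38 genes, median log2 fold change 0.15, camera adjusted p = 5.59e-05, and adjusted p = 0.568 with an estimated correlation), the mitochondrial ribosome (74 genes, median 0.11, camera adjusted p = 1.17e-04, and adjusted p = 0.79 with an estimated correlation) and epidermis (29 genes, median 0.12, camera adjusted p = 0.043, and adjusted p = 0.839 with an estimated correlation). The median of the mitochondrial ribosome was 0.03 without control pool 1 and 0.04 without knockout pool 1, and that of epidermis was 0.21, 0.04 and 0.23 without control pool 1, knockout pool 1 and knockout pool 3. The mitochondrial ribosome list did not pass without control pool 1 (camera adjusted p = 0.12), nor the cytosolic ribosome list without control pool 1 or knockout pool 1 (0.16 and 0.261). The epidermal list did not pass without control pool 2, control pool 3, knockout pool 1 or knockout pool 2 (0.145, 0.304, 0.906 and 0.0616), nor with upper-quartile scaling (0.0519). In autophagy 2 genes rose without control pool 1 and 1 without knockout pool 1. In the mitochondrial ribosome 3 genes rose with upper-quartile scaling, and 1 without a filter, without control pool 1 or without control pool 2. In epidermis 1 gene fell without knockout pool 1. At an unadjusted p under 0.05, 6 genes were higher and 1 lower in autophagy, 9 and 0 in the mitochondrial ribosome and 1 and 1 in epidermis. DESeq2 called 1 gene of these lists, higher in epidermis, and limma-voom 1, higher in the mitochondrial ribosome. Of the 23 lists called by camera, 8 had mean levels that overlapped between knockout and control pools: autophagy, cell cycle, both ribosome lists, epidermis, embryonic globins, lens and neurons.

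Genes of the mitochondrial genome did not move together. MT-ATP6 and mt-atp8, which code for subunits of the ATP synthase and overlap on one transcript, rose with log2 fold changes of 0.59 (SE 0.13, edgeR adjusted p = 0.0335) and 0.56 (SE 0.13, adjusted p = 0.0338). The other 11 protein genes stood between −0.38 (MT-CO1) and −0.15 (mt-nd4l), and none of them passed with edgeR (4 were lower and 0 higher at an unadjusted p under 0.05). DESeq2 called 3 of them lower, among them MT-CO1 (adjusted p = 0.00356) and MT-CO3 (0.0384), and limma-voom called 0. The ratio of MT-ATP6 counts to the summed counts of these 11 genes was 0.119 ± 0.00700 in the controls and 0.225 ± 0.0115 in the knockouts (mean ± SD, n = 3), 1.89-fold higher, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 pools allow. The share of counts from the 13 genes was 6.35 ± 0.391% in the controls and 5.83 ± 0.371% in the knockouts, a difference of −0.519 percentage points with overlapping pools (exact two-sided permutation p = 0.2, n = 3). The adjusted p of MT-ATP6 was 0.0571 to 0.191 when any of the 6 pools was left out, and that of mt-atp8 was 0.06 to 0.178 except without knockout pool 1 (0.0434). The list of all 13 genes did not pass camera (adjusted p = 0.0848), but passed as lower without control pool 1 or knockout pool 1 (0.0364 and 0.00911).

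**Figure D4:**
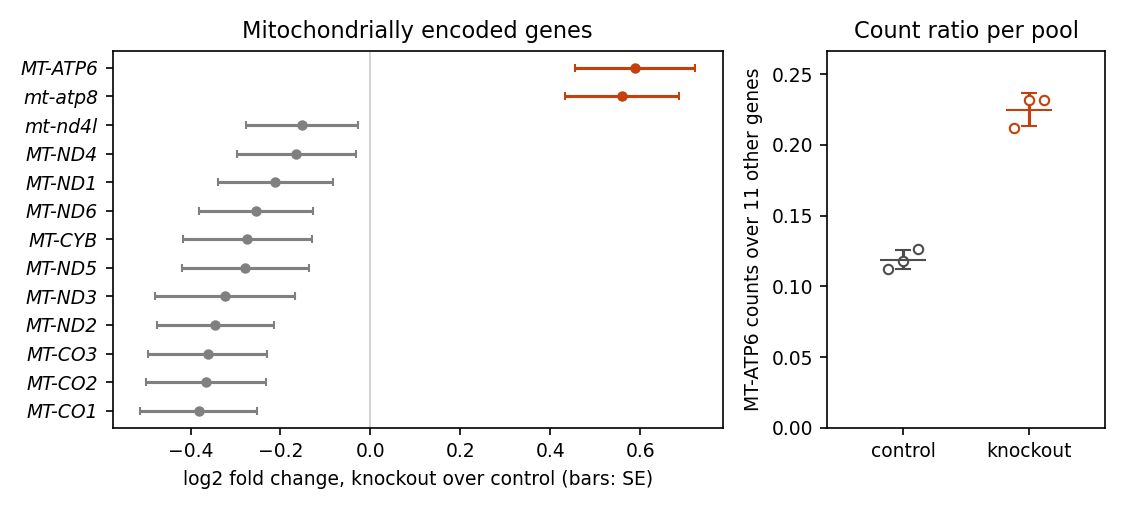
Left, log2 fold changes of the 13 mitochondrially encoded protein genes, knockout over control (bars are SE; coloured points, adjusted p under 0.05); right, the ratio of MT-ATP6 counts to the summed counts of 11 other mitochondrial genes in each pool (circles), with mean and SD. MT-ATP6 and mt-atp8 sit at 0.59 and 0.56, and the other 11 genes sit between −0.38 and −0.15.

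Nuclear genes of oxidative phosphorylation differed little. None of 38 complex I genes and none of 16 complex V genes passed with edgeR (1 lower in each at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom), with medians of 0.07 (0.01 to 0.14 with 1 pool left out) and 0.03 (−0.03 to 0.11) on the log2 scale, and 1 of 36 genes of complexes II to IV rose, the cytochrome c gene cycsb (0.51), which lost its call without any single pool other than knockout pool 1 (edgeR adjusted p = 0.0599 to 0.0919). Without knockout pool 1, 3 genes of that list fell. With the replicate block cycsb did not pass (edgeR adjusted p = 0.0706). The gene cox4i1l was lower with that block (edgeR adjusted p = 0.00669) and with DESeq2 (adjusted p = 0.0168). None of these 3 lists passed camera with the preset correlation (adjusted p = 0.0699, 0.713 and 0.548), nor did mitochondrial import (0.171), the tricarboxylic acid cycle (0.948) or fatty acid oxidation (0.689). The complex I list passed as higher without control pool 2, control pool 3, knockout pool 2 or knockout pool 3 (camera adjusted p = 0.00225, 0.0441, 0.0132 and 0.00496), and with upper-quartile scaling (0.0474) or without a filter (0.0403), and mitochondrial import without control pool 3 or knockout pool 2 (0.00979 and 0.0467).

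Of the 55 lists, 32 did not pass camera, with medians between −0.27 and 0.11 on the log2 scale, and in 10 of them the median, the mean and the direction of the test differed in sign. They covered, among others, fast muscle (43 genes), photoreceptors (70 genes), heart, cartilage and bone, pigment cells, endothelium, neutrophils and lymphoid cells, cytosolic heat shock proteins and the unfolded protein response of the endoplasmic reticulum. No gene of fast muscle or photoreceptors passed with edgeR or limma-voom. At an unadjusted p under 0.05, 1 fast muscle gene was higher and 1 lower, and 2 photoreceptor genes were higher and 9 lower. DESeq2 called 1 fast muscle gene higher, and 1 photoreceptor gene higher and 2 lower. Leaving out knockout pool 1 gave 1 higher fast muscle gene, leaving out control pool 1 gave 1 higher and 3 lower photoreceptor genes, and leaving out knockout pool 3 gave 1 lower photoreceptor gene. Within the 32 lists 25 genes rose and 13 fell. IGFBP1, which binds insulin-like growth factors, rose from 20.1 ± 6.82 CPM to 66.4 ± 12.1 CPM, and POMC, the precursor of corticotropin, from 9.57 ± 1.48 CPM to 25.9 ± 3.56 CPM. PKLR, the pyruvate kinase of liver and red cells, fell with a log2 fold change of −1.49 (SE 0.15), and XBP1, a transcription factor of the endoplasmic reticulum stress response, rose with a log2 fold change of 0.70. Without control pool 1 the lists of photoreceptors, pigment cells and the endoplasmic reticulum response passed as lower (camera adjusted p = 0.00385, 0.0496 and 0.00512), and those of cytosolic heat shock proteins, heart and hypoxia as higher (0.00458, 0.0249 and 0.0464). The endoplasmic reticulum response also passed as lower without knockout pool 1 (0.0256) and without a filter (0.047), and heat shock proteins as higher without knockout pool 2 (0.0457). Camera with an estimated correlation called 0 of the 55 lists (lowest adjusted p = 0.188). The test fry, which asks whether genes of a list move on balance in one direction, called 7, of which 5 were higher and 2 lower. Higher were cytosolic tRNA ligases, serine and one-carbon, p53 targets, mitochondrial chaperones and the integrated stress response (fry adjusted p = 0.0056 to 0.0107). Lower were hepatocytes and exocrine pancreas (0.0056 and 0.00915). The other 16 lists called by camera did not pass fry. Among these were intestine and erythroid (0.139 each), cell cycle (0.342), cholesterol synthesis (0.352) and lens (0.377).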

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

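Apart from the interferon list, whose alternative was chosen after the result was seen, all alternatives were set before the data were examined. No named gene past the threshold and no list called by camera changed direction under any alternative run, though medians near 0 of other lists changed sign. The count of 866 genes (317 higher, 549 lower) was 864 with RLE scaling, 891 with upper-quartile scaling (415 higher, 476 lower), 862 without a filter, 845 with a minimum of 1 CPM, 1090 with DESeq2 and 813 with limma-voom, and no gene shared with the 866 had the opposite sign. An adjusted p of 0.01 left 444 genes (156 higher, 288 lower) and a fold change of 2 left 389 (121 higher, 268 lower), both by construction. Leaving out 1 pool gave 549 to 981 genes, 189 to 346 higher and 360 to 635 lower, with fewer samples. The share of mitochondrial counts then differed by −0.737 to −0.321 percentage points. Of the fixed lists, camera called 23 (11 higher, 12 lower), 0 with an estimated correlation (0 higher, 0 lower), while fry called 7 (5 higher, 2 lower), and 21 to 28 were called with 1 pool left out. The preset correlation was 0.01, against an estimated 0.55 for exocrine pancreas, 0.30 for hepatocytes, 0.64 for cell cycle and 0.60 for cholesterol synthesis. The preset counts genes that vary together as nearly independent, so its p-values can overstate the evidence. Serine and one-carbon (0.04) and p53 targets (−0.03) had low estimates and did not pass with them either. Beyond these values, the cause was not tested. Of 138 named genes past the threshold, 92 stayed past it without each pool in turn and 46 did not in at least 1 such fit.

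The shared replicate numbers were not taken as pairs. Deviations of same-numbered pools correlated at −0.199, 0.10 and −0.0742, and only pool 2 correlated best with its own number. Yet on principal component 3 (12.9% of the variance) same-numbered pools lay close. Control and knockout stood at −18.2 and −18.1 (pools 1), 19.2 and 20.2 (pools 2), and −3.79 and 0.753 (pools 3). On component 2 (18.3%) they had opposite signs for each number. Whether the numbers mark mating sets thus stays open. With the replicate block 738 genes passed (251 higher, 487 lower), 683 of them shared with the 866, and 11 cholesterol synthesis genes were lower, against 2 without it. The planned test of calls near hspd1 was not run, because unique positions were found for 71.4% of tested genes, under a limit of 80%. The plan did not name that limit, and 80.3% of called genes had a unique position. At this depth and spread, the test on simulated data recovered 83 of 100 genes changed by 1 on the log2 scale.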

Other observations

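The count of splits was planned, as was the test near hspd1, and every other test here was chosen only after the results were seen. Among 383 families of genes whose symbols begin alike (766 tests), cytochrome P450 genes had the smallest p, with 21 of 75 lower (hypergeometric test, adjusted p = 5.48e-14), and 7 of the 75 were higher (adjusted p = 0.0225). Hepatocyte and intestinal markers moved with the lower ones (26 of 37 and 15 of 38 lower, median log2 fold changes −1.03 and −0.52), so a contribution of these tissues to the decrease stays open. CYP27B1, which activates vitamin D, fell from 7.73 ± 0.799 CPM to 1.22 ± 0.255 CPM (n = 3), CYP7A1, the first enzyme of bile acid synthesis, had a log2 fold change of −1.06, and cyp3a65 had −1.46. In the other direction cyp2aa7 rose from 17.5 ± 0.450 CPM to 126 ± 43.9 CPM and cyp3c3 had a log2 fold change of 1.75. Cerebellin-like genes were lower in 7 of 15 cases (adjusted p = 1.13e-05), among them cbln10 with a log2 fold change of −3.09. With 1 pool left out the counts were 15 to 20 for lower P450 genes and 5 to 7 for cerebellins. Genes are not independent replicates and members of a family can share reads, so these p-values describe this set of calls alone.

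The split of the 6 pools by genotype gave 866 genes and the highest of the other 9 splits gave 0. Thus 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. The other 9 splits put pools of both genotypes in each group. A difference between genotypes then adds to the spread within groups, so few calls there follow largely from the design. A haplotype around hspd1, shared by larvae sorted by genotype, could also change linked genes. That was not tested, with unique positions for 71.4% of tested genes. Which of the nuclear genes named lie near hspd1 is not given here, so it stays open for each of them.

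Of 37 hepatocyte genes 26 fell and of 34 acinar genes 28, and the hspd1 knockout may change the size of these organs or the expression within their cells. A smaller liver with unchanged hepatocytes predicts that no marker falls by more than fabp10a, if fabp10a is expressed in the liver only. Yet 6 of 37 fell by more: uox, hpxa, shbg, TTR, ahsg2 and GC, with intervals of 2 standard errors apart for all but ahsg2. With 0 reads in the knockouts, ahsg2 has no meaningful interval, but its bound of −6.88 on the log2 scale also lay below fabp10a. A smaller exocrine pancreas alone predicts 1 fold for all enzymes only if they are expressed in acinar cells alone, which was not checked. Over 30 enzyme genes Cochran's Q over its degrees of freedom was 21.6, with log2 fold changes from −4.47 to 0.30. The folds were thus unequal, but without that check they cannot tell a smaller organ from changed expression. Reduced size as part of the cause is not excluded by either test, and reads split between similar enzyme genes could add to the spread. Delay of the whole larva stays open too. The photoreceptor median was −0.12 (−0.19 to −0.03 with 1 pool left out), with a 95% interval of −0.24 to 0.03 that takes genes, not pools, as units. It neither reached a clear decrease nor excluded one. The mean levels of the pools overlapped, at −0.14 to 0.09 in the controls and −0.15 to 0.004 in the knockouts.

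Of 45 interferon-induced genes listed after the calls were seen, 29 rose and 0 fell (edgeR, median log2 fold change 1.83; 0 were lower at an unadjusted p under 0.05, by DESeq2 or by limma-voom), with 18 rising without control pool 3, and of the 8 in a list fixed beforehand 5 rose (median 2.23). More immune cells alone would raise macrophage, neutrophil and lymphoid markers by about the interferon median, if both sets were expressed in immune cells only. That was not checked. The immune markers had a median of 0.14 over 52 genes (95% interval −0.01 to 0.20). Macrophage markers taken alone had a median of 0.20 (95% interval 0.12 to 0.35, and 0.34 without knockout pool 2), which is below the interferon median. Their camera adjusted p was 0.00461, and the adjusted p = 0.246 with an estimated correlation. Their mean log2 levels were 0.18 to 0.35 in the knockout pools and −0.02 to 0.04 in the controls, and a contribution from more macrophages stays open. The intervals of these medians take genes as units, so they describe the spread among genes and not that between pools. If a single pool were affected, the other knockout pools would lie within the range of the controls. Mean levels of the 8 genes were 1.32, 2.63 and 2.49 in the knockout pools and −0.10 to 0.13 in the controls, a gap of 5.05 times the range of the controls. These genes were thus higher in all 3 knockout pools. As 5 of the 8 were called, and called genes had no overlap between groups, the gap followed in part from the choice of genes. Release of mitochondrial nucleic acids in the knockout, or an infection of all 3 knockout pools, may be candidate explanations, and neither was tested.

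MT-ATP6 and mt-atp8 stood apart from the other 11 mitochondrial genes. A change in genome copies or overall transcription would move all 13 alike, yet the ratio of MT-ATP6 to the others was higher in every knockout pool, with a gap of 6.13 times the range of the controls. This ratio was chosen after the single genes were seen and uses the same counts, so it restates their difference and is no separate evidence. Altered processing or polyadenylation of the shared transcript could cause this, in the cell or through poly(A) capture. These cannot be told apart, because 0 of the libraries were made without poly(A) selection.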
